A study of Macaca fascicularis
Homo sapiens with 2 samples.

How the data were processed

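The 2 deposited matrices hold UMI counts per gene and barcode from 10x Chromium 3' v3.1 libraries of pooled human H9 and cynomolgus 56A1 UGP2 knockout cells, 1 library at day 0 and 1 at day 7. Per the file headers the counts were made with Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 7.2.0 and GRCh38. The gene prefixes in the files name GRCh38 for 20669 human genes and Macaca_fascicularis 6.0, Ensembl release 107, for 22504 cynomolgus genes. Mapping settings are not given in the sources used here. Of the cynomolgus genes, 7329 have an identifier and no symbol, and 0 of these matched the reference gene table used here, which is of another cynomolgus assembly and served only to see which genes are neighbours. A symbol is given once in both species for 15146 genes.

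Barcodes with at least 1000 UMIs over both genomes, 500 genes and at most 20% mitochondrial UMIs were kept. A barcode was called human with at least 90% of its UMIs on the human genome, cynomolgus with at most 10%, and otherwise left out as neither. Doublets of cells of 1 species were not removed and no doublet caller was run. An alternative left out the 5% of cells with the most UMIs. UMIs were summed over the cells of a species and day, giving 34670316 and 43723892 own-species non-mitochondrial UMIs in human cells and 10683788 and 34639499 in cynomolgus cells on days 0 and 7. Values are CPM of that total, and changes are log2((CPM day 7 + 1)/(CPM day 0 + 1)), which understates the change of low genes. A count of 0 was set against a floor of 3 counts, 0.0865 and 0.0686 CPM in human and 0.281 and 0.0866 CPM in cynomolgus cells.

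Before the data were examined, 24 gene lists, the cell type markers, the alternatives and the rule for named genes were fixed. The rule takes genes with a symbol, not mitochondrial or ribosomal protein genes, at 50 CPM or more on either day, and names the 10 largest increases and 10 largest decreases per species. Between species it takes symbols given once in both annotations, at 50 CPM or more in at least 1 of the 4 groups and 5 CPM or more on either day in both species, and names the 10 largest and 10 smallest differences. UGP2 and list members are named besides these. A result that met this rule is not reported here. List members needed 5 CPM on either day. With 1 library per day no test was run. Single values have exact Poisson or exact binomial 95% intervals, and list medians have intervals from 1000 Poisson draws. For r, 200 draws were used and their spread was centred on the observed value, because redrawing counts adds noise and lowers r. This centring was chosen after the mean of the draws, 0.674, was seen to lie below r. List counts are of members at least 2-fold higher or lower, a description of size.

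For shares of cells with a UMI, each cell was thinned to 2500 own-species UMIs, which left out 516 and 410 human and 19 and 510 cynomolgus cells on days 0 and 7. Each species and day was clustered alone (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5). The cluster naming rule was set after the data were seen and its result changed with resolution, so clusters are referred to by number. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used. The day 7 against day 0 step was tested on simulated data with 200 genes changed 2-fold either way. Over 5285 genes of human cells it gave median log2 changes of 0.97 and -1.00 for these genes and -0.01 for unchanged genes, and over 5268 genes of cynomolgus cells 0.98, -0.99 and -0.01. The simulated counts were Poisson draws from a single pooled profile per species, so they check the arithmetic only. They held no reads mapped to the other genome, no mixed barcodes and no mixture of cell types. The alternatives covered the species call, UMI and mitochondrial limits, the CPM total and its scaling, equal weight per cell, the pseudocount, the minimum level, the thinning depth and the cluster resolution. Rescaling day 7 by the median ratio shifted changes by 0.01 on the log2 scale in both species.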

Results

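Single-cell RNA profiles were collected from UGP2 knockout lines of 2 primates at the start of neural induction and after 7 days of it. UGP2 encodes the enzyme that makes UDP-glucose, the sugar donor for glycogen synthesis. The human cells were H9, an embryonic stem cell line, and the cynomolgus macaque cells were 56A1, an induced pluripotent stem cell line. Per the labels, cells of both species were pooled in equal amounts at each time point, so each day is 1 library and the species of a cell was read from the genome its UMIs mapped to. Neural induction used SB431542 at 10 µM and LDN193189 at 100 nM, inhibitors of NODAL/activin and BMP receptors. The day 0 library held 12093 barcodes and 71377836 UMIs, with a median of 5524 UMIs per barcode. The day 7 library held 16403 barcodes and 99430745 UMIs, with a median of 5177. With 1 library per day there were no replicates and no test was possible, so intervals cover counting error only and differences describe these libraries. The series as used here held no UGP2 wild-type cells, so no effect of the knockout was measured.

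The day 0 library gave 5206 human and 2016 cynomolgus cells, and the day 7 library gave 8173 and 6467. Human cells were 72.1% of species-called cells on day 0 (exact binomial 95% interval 71.0% to 73.1%) and 55.8% on day 7 (55.0% to 56.6%). The day 0 share depended on the calling rule. At day 0, 4473 of 11695 barcodes that passed the filters (38.2%) were called neither species, and 2450 of them had 10% to 20% human UMIs. Calling species at 80% instead of 90% of UMIs gave 4466 cynomolgus cells and a human share of 55.1% on day 0. On day 7, 1476 of 16116 barcodes (9.16%) were called neither species. Cynomolgus cells carried a median of 9.003% human-genome UMIs on day 0 and 6.01% on day 7, against 2.11% and 1.22% cynomolgus-genome UMIs in human cells. The call allowed cynomolgus cells at most 10% human UMIs, a limit that cut through their peak on day 0. The day 0 median is therefore bounded by the rule and is not on a par with the day 7 median.

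**Figure D1:**
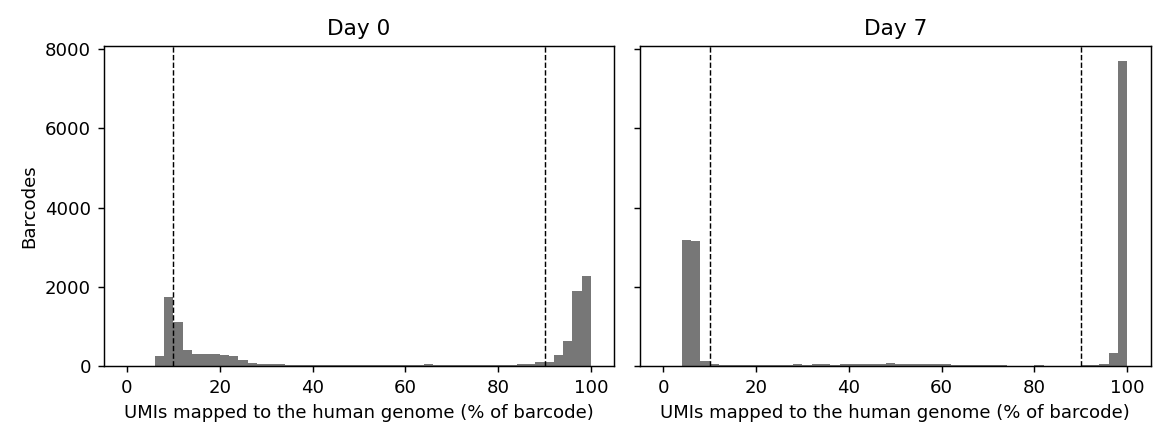
Histograms of the percent of each barcode's UMIs that mapped to the human genome, in bins of 2 percentage points, for barcodes that passed the filters on each day; dashed lines mark 10% and 90%. On day 0 the line at 10% runs through the cynomolgus peak, while on day 7 both peaks lie outside the lines.

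UGP2 transcript was counted in both lines and was lower on day 7 in both. In human cells UGP2 (ENSG00000169764) was at 216.6 CPM on day 0 (exact Poisson 95% interval 211.7 to 221.6) and 87.0 CPM on day 7 (84.3 to 89.8), a log2 change of -1.31. In cynomolgus cells UGP2 (ENSMFAG00000035944) was at 326.9 CPM on day 0 (316.1 to 337.9) and 76.8 CPM on day 7 (73.9 to 79.8), a log2 change of -2.08. A 3' tag count does not check the knockout unless the deleted part is the counted part, which the labels do not state.

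The first question was what differed between day 7 and day 0 in human cells. Pluripotency genes were far lower on day 7 and neural progenitor genes far higher. POU5F1, a core pluripotency factor, was at 1205 CPM on day 0 and 2.86 CPM on day 7. TDGF1, a NODAL co-receptor, was at 191.1 CPM on day 0 and had 0 UMIs on day 7, at least 2785-fold lower against a floor of 3 counts over the group. DLK1, a non-canonical Notch ligand, was at 23.1 CPM on day 0 and 2407 CPM on day 7, and the nuclear receptor NR2F2 at 0.375 and 67.7 CPM. On day 0 DLK1 lay mostly in a cluster of 418 cells, at 370.6 CPM there and 1.78 CPM in other cells. Of 21 measured pluripotency genes, 17 were at least 2-fold lower on day 7, 0 were at least 2-fold higher and 4 lay in between, with a median log2 change of -2.92 (counting interval -2.98 to -2.88). Of 25 measured neural progenitor genes, 18 were at least 2-fold higher, 1 was at least 2-fold lower and 6 lay in between, with a median of 2.45 (2.39 to 2.60). Without that cluster, which carried neural progenitor markers and was left out after seeing the data, the neural progenitor median was 3.41. SIX3, SIX6 and DACH1, members of this list, are among the cluster's leading genes, so leaving it out raises their change by construction. The 2 medians were at percentiles 0 and 100 among 10000 random lists of the same size matched on mean expression, a description of these libraries.

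Within the human pluripotency list, NANOG was at 39.6 CPM on day 0 and 0.709 CPM on day 7 and ZFP42 at 96.0 and 5.44 CPM. Other members kept part of their level. L1TD1, an RNA-binding protein of pluripotent cells, was at 1225 CPM on day 0 and 267.9 CPM on day 7, DPPA4 at 523.5 and 112.2 CPM and the DNA methyltransferase DNMT3B at 552.4 and 113.8 CPM. LIN28A was at 359.0 and 226.7 CPM. Among neural progenitor genes, PAX6 was at 0.808 CPM on day 0 and 49.6 CPM on day 7 (12.95 CPM in that day 0 cluster and 0.0612 CPM in other day 0 cells), SIX3 at 25.5 and 141.9 CPM (397.5 CPM in that day 0 cluster and 2.60 CPM in other day 0 cells), SOX11 at 107.6 and 663.5 CPM and the radial glial fatty acid binding protein FABP7 at 28.5 and 316.5 CPM. HESX1 was lower on day 7, at 72.3 and 20.6 CPM. Of the other genes with the largest increases, HPSE2 was at 3.72 and 241.9 CPM, TXNIP at 16.7 and 889.5 CPM and the growth factor FGF8 at 4.27 and 263.2 CPM. LIX1, LRP2, MEIS2, PRSS23 and GREB1L completed the 10, with log2 changes from 4.82 to 5.23; GREB1L was at 589.3 CPM in that cluster and 8.17 CPM in other day 0 cells. Of the largest decreases, MGAT4C was at 207.2 and 0.252 CPM, the tight junction protein CLDN7 at 132.6 and 0.274 CPM and the neuropeptide GAL at 173.1 and 0.800 CPM. RARRES2, ADCY2, CD9 and FLT1 had log2 changes from -6.70 to -6.14.

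Of the inhibited pathways, targets of NODAL and activin were lower in human cells and targets of BMP went both ways. All 7 measured NODAL and activin targets were at least 2-fold lower, with a median log2 change of -3.48, among them LEFTY1 at 11.2 and 0.0915 CPM. NANOG and TDGF1 are among these 7 and also in the pluripotency list, so the count partly repeats the pluripotency result. Outside that list, FOXH1 was at 77.3 and 1.235 CPM and SKIL at 136.6 and 24.1 CPM. Of 8 BMP targets, 4 were at least 2-fold lower, such as ID1 at 174.2 and 21.6 CPM, and 3 were at least 2-fold higher, such as ID4 at 9.11 and 55.1 CPM. Of 18 integrated stress response genes, 12 were at least 2-fold lower (median -1.51), including the asparagine synthetase ASNS at 89.6 and 15.3 CPM, while DDIT4 was higher at 66.8 and 335.4 CPM. Of 29 oxidative phosphorylation genes, 10 were at least 2-fold lower (median -0.80), including cytochrome c, CYCS, at 486.7 and 115.5 CPM. The glycogen metabolism list, which holds UGP2, had 5 of 24 members at least 2-fold higher and 4 at least 2-fold lower (median 0.22, interval 0.12 to 0.25). Its branching enzyme GBE1 was at 22.7 and 72.5 CPM and its glycogenin GYG1 at 40.7 and 17.45 CPM. The glycogen median was 0.0336 when members needed 20 CPM.

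In cynomolgus cells the same question gave the same broad picture for the neural progenitor genes, with fewer pluripotency genes to read. PAX6 was at 0.281 CPM on day 0 and 105.0 CPM on day 7, DLK1 at 5.15 and 1903 CPM and NR2F2 at 0.374 and 122.7 CPM. BARHL1 had 0 UMIs on day 0 and 57.9 CPM on day 7, at least 206-fold higher against a floor of 3 counts over the group. L1TD1 was at 185.6 CPM on day 0 and 0.231 CPM on day 7, and DPPA4 at 172.4 and 0.260 CPM. Of 21 neural progenitor genes, 19 were at least 2-fold higher and 1 at least 2-fold lower (median 3.25, interval 3.17 to 3.36). A day 0 cluster of 92 of 2016 cynomolgus cells (4.56%) also carried neural progenitor markers. The neural progenitor median was higher without it, as given with the other processing settings below. LHX2 and CDH2, members of the list, are among that cluster's leading genes, so leaving it out raises their change by construction. Of 12 measured pluripotency genes, 6 were at least 2-fold lower, 1 was at least 2-fold higher and 5 lay in between (median -1.64, interval -1.68 to -1.60). POU5F1, NANOG, TDGF1, UTF1 and PODXL have no cynomolgus gene of that symbol in the files. The pluripotency median was -0.77 with members of at least 20 CPM. With the counts of both genomes' copies summed, a setting chosen after the data were seen, it was -1.64 over the same 12 members and -3.14 over 19, the others, such as POU5F1 and FOXD3, measured in cynomolgus cells mainly through human-genome UMIs. Human-copy TDGF1 in cynomolgus day 0 cells was at 1.4% of its UMIs in human cells, near the 1.5% of human mitochondrial UMIs. Members read this way can follow the pooled human cells, so -3.14 is not read as a cynomolgus change.

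Among the other cynomolgus genes with the largest increases, the Wnt sorting receptor WLS was at 6.46 and 577.9 CPM, SOX6 at 3.09 and 261.9 CPM and the cell adhesion molecule CNTN6 at 1.12 and 223.5 CPM. PTX3, NR2F1 and CDH8 had log2 changes of 5.99, 5.97 and 5.69. Among the decreases, IFITM1 was at 557.1 and 0.924 CPM, the secreted phosphoprotein SPP1 at 188.3 and 0.520 CPM and E-cadherin, CDH1, at 162.6 and 2.19 CPM. CCHCR1 was at 651.5 and 8.29 CPM, and ITM2A, BCL11A, AP1M2 and KCTD8 had log2 changes from -6.60 to -5.65. Of 15 hypoxia genes, 12 were at least 2-fold higher (median 1.91, interval 1.79 to 2.01), such as the prolyl hydroxylase P4HA1 at 69.6 and 477.9 CPM and BNIP3 at 244.3 and 664.6 CPM. ADM and ANKRD37, members of this list, are among the leading genes of day 7 clusters 2 and 5, so leaving these clusters out must lower such genes. The clusters hold 1875 of 6467 cells and were left out after seeing the data. Without them, 9 of 15 hypoxia genes were at least 2-fold higher and the median was 1.12. Of 11 FGF and ERK targets, 4 were at least 2-fold lower (median -0.92), with DUSP6 at 317.8 and 11.2 CPM and ETV4 at 131.4 and 4.56 CPM. Of 18 cholesterol synthesis genes, 9 were at least 2-fold lower (median -0.9995). The glycogen metabolism list had 3 of 16 members at least 2-fold higher and 1, UGP2, at least 2-fold lower (median -0.05, interval -0.17 to 0.10).

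**Figure D2:**
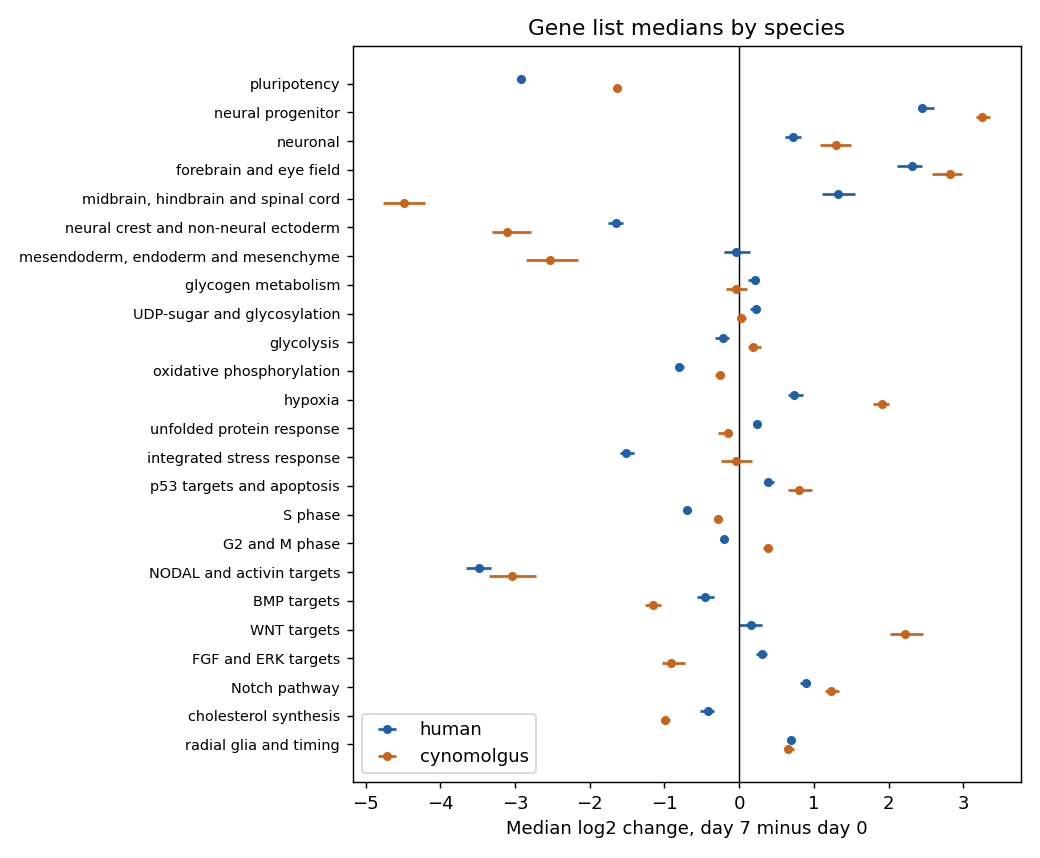
Median log2 change from day 0 to day 7 of each gene list in human and cynomolgus cells; bars are 95% intervals from 1000 Poisson draws and cover counting error only. Medians rest on each species' own measured members, 1 to 29 per list, so points of a list do not always compare the same genes.

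The second question was how the day 7 minus day 0 change differed between the species, each represented by 1 line. Over 9094 genes measured in both species the log2 changes had Pearson r = 0.68 and Spearman rho = 0.67 across genes, which are not independent replicates. Both species had 653 of these genes at least 2-fold higher and 557 at least 2-fold lower, while 27 were at least 2-fold higher in human and lower in cynomolgus cells and 42 the other way round. The pluripotency genes L1TD1 and DPPA4 had log2 changes of -2.19 and -2.21 in human cells and -7.24 and -7.11 in cynomolgus cells. POLR3G, of the same list, went the other way, at -4.75 in human and -0.70 in cynomolgus cells. THRB, a thyroid hormone receptor, was at 16.2 and 0.869 CPM in human cells and 0.936 and 78.9 CPM in cynomolgus cells. The peptide hormone ADM, a hypoxia gene, was at 54.8 and 5.51 CPM in human cells and 4.40 and 44.5 CPM in cynomolgus cells.

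The signed log2 change of all 13 hypoxia genes measured in both species was higher in cynomolgus cells, with a median difference of 0.79 (counting interval 0.61 to 0.87). In human cells 6 of 14 hypoxia genes were also at least 2-fold higher on day 7 and 1 was at least 2-fold lower (median 0.73). P4HA1 had log2 changes of 2.63 in human and 2.76 in cynomolgus cells. ADM and ANKRD37, members of this list, are among the leading genes of cynomolgus day 7 clusters 2 and 5. Leaving these clusters out in cynomolgus cells only, done after seeing the data, therefore lowers the difference by construction. Without them the median difference was -0.0228, with 6 of 13 higher, and ADM was at 5.27 CPM in cynomolgus day 7 cells. This locates high hypoxia genes within the cynomolgus cells and is no test of the difference between species. The signed change was higher in cynomolgus cells for 12 of 14 integrated stress response genes (median difference 0.97), such as ASNS with log2 changes of -2.48 in human and -0.50 in cynomolgus cells. It was higher for 18 of 19 G2 and M phase genes (0.59) and for 1 of 11 FGF and ERK targets (median difference -1.25), such as DUSP6 at -1.64 in human and -4.71 in cynomolgus cells. Oxidative phosphorylation genes (19 of 20, median difference 0.46) and S phase genes (17 of 20, 0.35) were also mostly higher. The share of all shared genes with a higher change in cynomolgus cells is not given here, so these counts have no baseline. The difference was 0.49 for the 12 shared pluripotency genes (counting interval 0.33 to 0.56). Of these, 8 were higher, 4 were at least 2-fold above and 3 at least 2-fold below. The interval of this median across members was -1.37 to 1.2, so the members do not settle its sign. The pluripotency difference was 0.82 with no minimum level and 0.30 with a pseudocount of 0.1. The difference was 0.30 for the 18 shared neural progenitor genes (counting interval 0.18 to 0.54, across members -0.88 to 1.115). Of these, 5 were at least 2-fold above and 4 at least 2-fold below. The neural progenitor difference has no settled sign either, and it was -0.26 with species called at 80% of UMIs.

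Of the other genes furthest above the human change, TFPI, TUBB2A, TMEM132B and HS3ST5 differed by 5.84, 5.65, 5.20 and 5.14 on the log2 scale. With both genomes' copies summed, the difference was 4.11 for TUBB2A, -3.37 for LRRTM4, -3.68 for L1TD1, -3.46 for DPPA4, -5.05 for CCHCR1 and -7.25 for IFITM1. The receptor ERBB4 was at 17.1 and 17.7 CPM in human cells and 18.9 and 650.6 CPM in cynomolgus cells, and PTX3 and CDH8 differed by 4.79 and 4.70. Of those furthest below, IFITM1 and CCHCR1 differed by -8.43 and -6.61. IL1RAPL1 was at 61.6 and 603.4 CPM in human cells and 289.2 and 96.1 CPM in cynomolgus cells. LRRTM4, HPSE2, PAMR1, DGKB and CPNE8 differed by -4.85, -4.62, -4.47, -4.46 and -4.45.

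**Figure D3:**
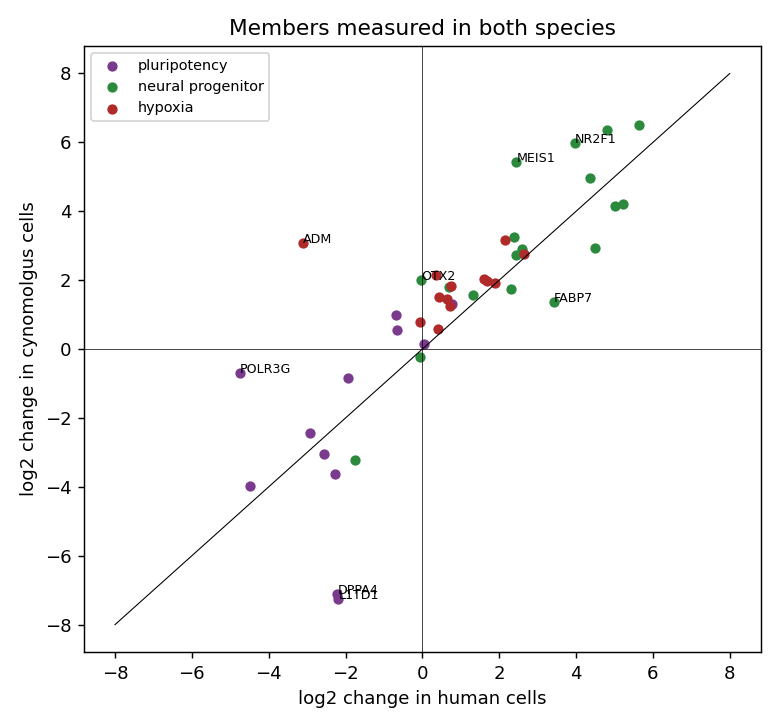
Log2 change from day 0 to day 7 in human cells (x axis) and cynomolgus cells (y axis) of pluripotency, neural progenitor and hypoxia genes measured in both species; the line marks equal change, and genes at least 2 apart are named. L1TD1 and DPPA4 lie furthest below the line, and ADM lies furthest above it.

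Single cells were thinned to 2500 own-species UMIs to compare shares of cells with a UMI. On day 7, 0.721% of 7763 human cells had a POU5F1 UMI (exact binomial 95% interval 0.545% to 0.936%), against 91.2% of 4690 on day 0, when the human copy was also seen in 39.1% of cynomolgus cells. The human copy was seen in 0.0336% of cynomolgus day 7 cells, the background. On day 7, 46.5% of human cells had an L1TD1 UMI, with 0.772% of cynomolgus cells carrying the human copy, and 0.0839% of 5957 cynomolgus cells had an L1TD1 UMI of their own copy. PAX6 was seen in 11.5% of human day 7 cells (10.8% to 12.2%) and 21.7% of cynomolgus day 7 cells (20.7% to 22.8%). The cynomolgus copy of PAX6 was seen in 0.283% of human cells. The human copy of PAX6 was seen in 17.9% of cynomolgus cells, above its share in human cells, so the human PAX6 share has no usable background of this kind. Cynomolgus day 7 cells held 2934 UMIs of the human copy beside 3638 of their own, so their PAX6 share and CPM on day 7 are too low, and with both copies summed PAX6 was at 178.1 CPM. In human day 0 cells PAX6 was seen in 0.299%. Unthinned, the day 7 shares were 1.49% for POU5F1, 66.4% for L1TD1 and 21.7% for PAX6 in human cells and 39.0% for PAX6 in cynomolgus cells, at median own-species depths of 4769 and 4596 UMIs.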

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

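Both tests of L1TD1 and DPPA4 were chosen after related results had been seen. Differences between species were not tested, since each species and day is 1 group of cells from 1 library. Of the genes with the largest differences between species, those at least 2-fold apart between days in opposite directions are given first. Cynomolgus minus human log2 differences were 8.57 for THRB, 6.17 for ADM, 5.84 for TFPI, 5.65 for TUBB2A, 5.20 for TMEM132B, 5.14 for HS3ST5, -4.85 for IL1RAPL1, -4.85 for LRRTM4 and -4.46 for DGKB. Shared members of 4 gene lists had medians of opposite sign in human and cynomolgus cells, which was not tested either: glycogen metabolism (0.13 and -0.05, median difference -0.14, counting interval -0.29 to 0.02, which includes 0), glycolysis (-0.17 and 0.18, difference 0.25), unfolded protein response (0.30 and -0.14, difference -0.65) and G2 and M phase (-0.19 and 0.38, difference 0.59). Barcodes called neither species, which no comparison used, numbered 4473 on day 0 and 1476 on day 7.

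The human copy of POU5F1, outside the cynomolgus measurement, had 2052 UMIs in cynomolgus day 0 cells, 4.91% of its UMIs in human cells, while human mitochondrial UMIs in the same cells were at 1.54% and TDGF1 at 1.37%. CCHCR1, a neighbour of POU5F1 in the reference gene table, was far lower on day 7 in cynomolgus but not in human cells. Movement of CCHCR1 reads to the human copy is argued against, since with both copies summed the log2 change was still -5.99. A candidate explanation is that reads of POU5F1 were counted as CCHCR1: across cynomolgus day 0 cells CCHCR1 correlated with human-copy POU5F1 above 99.7% of 329 genes of like level, although r was only 0.0957. A gene regulated together with POU5F1 would score as high, so regulation of CCHCR1 itself stays open.

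L1TD1 and DPPA4 kept 21.7% of their day 0 CPM, on average, in human day 7 cells and almost none in cynomolgus cells. A minority of undifferentiated human cells is argued against, since POU5F1 kept 0.237% where L1TD1 kept 21.9%. Loss of cynomolgus reads to the human copies is argued against as well, since with both copies summed the genes kept 1.35% in cynomolgus cells. A difference between the species may remain, as may one between the lines or their culture, and with 1 line per species these were not separated. L1TD1 and DPPA4 do not stand for the pluripotency list. POLR3G went the other way, at 269 and 9.03 CPM in human and 114.5 and 70.1 CPM in cynomolgus cells. Of the 12 shared pluripotency genes, 8 had a higher signed change in cynomolgus cells.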

How the results depend on the processing

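No paired analysis was possible because each day is 1 library and no test was run. Under the settings fixed beforehand, 110 values of the main results stayed within the counting interval, 44 moved beyond it and 1 changed sign; under settings chosen after seeing the data these numbers were 48, 9 and 2. The settings chosen after seeing the data are named as such below. The planned share of cynomolgus day 7 cells with a POU5F1 UMI was not computed, since the files give no cynomolgus gene of that symbol. At 95% of UMIs 0 cynomolgus day 0 cells remained, so no cynomolgus change was computed. The cause of the other movements was not tested.

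The neural progenitor difference between species changed sign with species called at 80% of UMIs (-0.26), at 80% with at least 2000 UMIs (-0.18, chosen after seeing the data) and without the day 0 clusters with neural progenitor markers (-0.0056, likewise). The share of human cells on day 0 was 55.1% at 80%, 100.0% at 95%, 71.0% with 2000 UMIs and, chosen after seeing the data, 69.8% without low-UMI clusters and 56.3% at 80% with 2000 UMIs; on day 7 it was 98.6% at 95%. At 80% the neural progenitor medians were 2.39 in human and 2.78 in cynomolgus cells, and 2.76 in cynomolgus cells with 2000 UMIs as well, where r was 0.67. Without the day 0 clusters with neural progenitor markers they were 3.41 and 3.79, and r was 0.69. Members of the list lead these clusters, so leaving the clusters out raises the members' changes by construction, which also bears on the -0.0056 above. With mitochondrial genes in the total, log2 changes were -1.24 for human UGP2, -2.85 for human pluripotency and 0.28 for human glycogen genes. With each cell counted alike, these were -1.22 for human UGP2, 2.26 for human neural progenitor and 0.25 for human glycogen genes, the neural progenitor difference was 0.84 and r 0.67. A pseudocount of 0.1 gave neural progenitor medians of 2.62 and 4.43, differences of 0.30 for pluripotency and 0.60 for neural progenitor genes and r of 0.68. A pseudocount of 5 gave pluripotency medians of -2.50 and -1.34, neural progenitor medians of 2.19 and 2.05, a difference of 0.11 and r of 0.67. With no minimum level, pluripotency medians were -2.84 and -1.05, neural progenitor medians 2.35 and 2.91, the human glycogen median 0.0370, the pluripotency difference 0.82 and r 0.59. At 20 CPM the cynomolgus pluripotency median was -0.77, the human glycogen median 0.0336 and r 0.72, and medians that changed sign were -0.32 for neuronal genes, -0.87 for WNT targets and -0.0428 for FGF and ERK targets in human cells and 4.46 for mesendoderm, endoderm and mesenchyme genes in cynomolgus cells. The WNT value is the change of ZNRF3 alone. The value 4.46 is the largest change of any member of its list, in which 4 of 5 members were at least 2-fold lower. Neither value describes its list. With both gene copies summed, chosen after seeing the data, which also adds members measured only with both copies, the cynomolgus pluripotency median was -3.14 and r 0.71, and medians that changed sign were 0.38 for mesendoderm, endoderm and mesenchyme genes in human and -0.80 for glycolysis genes in cynomolgus cells; over the unchanged members these 3 medians were -1.64, -0.0696 and 0.21. Shares with a UMI followed depth: at 1250, 5000 and all UMIs POU5F1 was at 0.383%, 1.62% and 1.49% of human cells, PAX6 at 6.06%, 19.3% and 21.7% of human cells and PAX6 at 11.7%, 40.0% and 39.0% of cynomolgus cells. The share of day 7 cells in clusters named by neural progenitor markers was 55.2%, 53.04% and 98.4% in human and 93.8%, 63.1% and 85.5% in cynomolgus cells at resolutions 0.5, 0.25 and 1, so no share of a named class is reported.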

Other observations

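In human cells the Notch effector HES5 was at 0.231 CPM on day 0 and 26.9 CPM on day 7 and the ligand DLL1 at 5.31 and 32.9 CPM, while HEY2 was at 19.4 and 0.183 CPM. In cynomolgus cells DLL1 was at 1.498 and 73.4 CPM and JAG1 at 12.3 and 56.7 CPM. In cynomolgus cells 4 of 6 measured WNT targets were at least 2-fold higher, with LEF1 at 4.21 and 68.4 CPM and LGR5 at 0.187 and 32.1 CPM. In human cells 2 of 6 measured WNT targets were, with LEF1 at 0.865 and 15.4 CPM, while AXIN2 was lower at 7.50 and 2.54 CPM. Only 5 WNT targets were measured in both species, so the 2 counts do not cover the same genes. The human WNT median stood at percentile 54.0 among the random lists. Neuronal genes went both ways. TUBB3 was at 7.39 and 79.0 CPM in cynomolgus cells, while 0.384% and 0.361% of thinned human cells had a TUBB3 UMI on days 0 and 7. MAP2 was at 36.0 and 517.4 CPM in human and 56.6 and 180.4 CPM in cynomolgus cells. SYT1 was at 452 and 752.6 CPM in human cells but at 717.0 and 190.9 CPM in cynomolgus cells. GAP43 was at 25.4 and 8.42 CPM in human and 21.5 and 5.745 CPM in cynomolgus cells. NFIA, a factor of later glial stages, was lower on day 7 in both, at 15.2 and 4.78 CPM in human and 160.1 and 6.06 CPM in cynomolgus cells. Of 20 S phase genes, 4 were at least 2-fold lower in human cells and 0 in cynomolgus cells.

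The other lists in human cells had these numbers of members at least 2-fold higher and at least 2-fold lower, with the median log2 change: neuronal 4 and 3 of 10 (0.72), forebrain and eye field 4 and 1 of 7 (2.31), midbrain, hindbrain and spinal cord 2 and 0 of 3 (1.33), neural crest and non-neural ectoderm 1 and 3 of 6 (-1.65). Further values were mesendoderm, endoderm and mesenchyme 0 and 1 of 3 (-0.0372), UDP-sugar and glycosylation 1 and 4 of 26 (0.22), glycolysis 2 and 4 of 23 (-0.21), hypoxia 6 and 1 of 14 (0.73). These were followed by unfolded protein response 1 and 0 of 18 (0.24), p53 targets and apoptosis 5 and 3 of 18 (0.38), S phase 0 and 4 of 20 (-0.70), G2 and M phase 0 and 2 of 20 (-0.20). Next came WNT targets 2 and 1 of 6 (0.15), FGF and ERK targets 4 and 3 of 13 (0.31), Notch pathway 6 and 2 of 14 (0.89), cholesterol synthesis 0 and 6 of 20 (-0.42). The last was radial glia and timing 4 and 3 of 14 (0.70). The other lists in cynomolgus cells had these numbers of members at least 2-fold higher and at least 2-fold lower, with the median log2 change: neuronal 6 and 3 of 10 (1.30), forebrain and eye field 7 and 1 of 8 (2.81), midbrain, hindbrain and spinal cord 0 and 1 of 1 (-4.49), neural crest and non-neural ectoderm 1 and 5 of 7 (-3.10). Further values were mesendoderm, endoderm and mesenchyme 1 and 4 of 5 (-2.53), UDP-sugar and glycosylation 3 and 2 of 26 (0.0216), glycolysis 4 and 3 of 14 (0.18), unfolded protein response 0 and 2 of 17 (-0.14). These were followed by p53 targets and apoptosis 6 and 0 of 13 (0.80), S phase 1 and 0 of 20 (-0.29), G2 and M phase 2 and 0 of 19 (0.38), WNT targets 4 and 0 of 6 (2.23). Next came Notch pathway 4 and 1 of 8 (1.24), radial glia and timing 4 and 2 of 12 (0.66), integrated stress response 2 and 3 of 14 (-0.0372), oxidative phosphorylation 0 and 0 of 20 (-0.26). The rest were NODAL and activin targets 0 and 3 of 3 (-3.04), BMP targets 2 and 4 of 7 (-1.15). With members of at least 20 CPM the sign turned for neuronal genes (-0.32), WNT targets (-0.87) and FGF and ERK targets (-0.0428) in human cells and for mesendoderm, endoderm and mesenchyme genes (4.46) in cynomolgus cells. The WNT value is the change of ZNRF3 alone, and 4.46 is the largest change of any member of its list, so neither describes its list.

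Most tests of human day 0 cluster 6 were chosen after the cluster had been seen. It held 418 of 5206 cells (8.03%), with SIX3 at 397.5 CPM and POU5F1 at 385.6 CPM, against 2.60 and 1256 CPM in other day 0 cells, and at resolution 1 clusters of 219 and 201 cells had neural progenitor markers, of which only the second met the detection rule for pluripotency markers as often as for neural progenitor markers. Free RNA of day 7 cells is argued against, since it has their average composition and 41 of 4431 genes were at least 2-fold above both day 7 and other day 0 cells, such as RIPPLY3 at 386.1 CPM against 10.2 and 4.13 CPM. Day 7 cells of a minority type are argued against, since only 3 human day 7 cells reached the cluster's median share of these genes, 0.699% of UMIs; 50 genes were also 2-fold above the 81 most similar day 7 cells, which differed little from the day 7 average. Doublets are argued against by a median UMI count 0.659 times that of other human day 0 cells, and differentiating cells of the day 0 culture may remain, which the design gives no group to test.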
